A study of Homo sapiens with 6 samples.

How the data were processed

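Ribosome profiling (Ribo-seq) libraries were analysed from the human embryonic stem cell line H9: undifferentiated human embryonic stem cells (hESC), neuroepithelial progenitors (NEP) and mesendoderm cells (ME), with 2 libraries per group and 6 in all. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, translating ribosomes were fixed in place with 100 µg/ml cycloheximide for 5 min, lysates were digested with RNase I for 45 min, fragments longer than 17 nt were purified, rRNA was removed with antisense DNA probes and RNase H, and libraries were made with a small RNA kit. No RNA-seq library was used here, so a change in footprints joins changes in mRNA abundance and in translation, and no translational efficiency was computed.

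Per the submitters' processing notes, the tools used were fastp, Bowtie2, STAR, RSEM and DESeq2, with the human genome builds GRCh38 and hg38. Their versions, roles and order are not given in the sources used here. There are 2 deposited tables, 1 for NEP and hESC and 1 for ME and hESC. Each deposited table holds an expected count per gene and library that the authors rounded to whole numbers. Across both tables, 5 entries pair a count of 0 with an FPKM above 0, as rounding of estimated counts gives. Each deposited table also holds FPKM per library, and the authors averaged it per group and wrote 0.001 in place of a mean of 0. The deposited log2 value is the log2 ratio of those 2 mean FPKM values, not the output of a count model. The deposited p-value and FDR are the authors' own. Both tables hold only genes that the authors had selected: the smallest absolute log2 ratio was 1.001 in the NEP table and 1.002 in the ME table, and the largest FDR was 0.05 and 0.0496. The ratio of FDR to p for the first gene gives 14366 genes tested by the authors for NEP and 13594 for ME, of which 2675 and 1211 are in the tables. All other genes, NAT10 among them, were not analysed here. A gene was named by its symbol in the tables, or by its Ensembl identifier in the 45 and 24 cases without a symbol. Biotype and coordinates came from the RefSeq annotation of GRCh38.p14, matched by symbol for 2591 of 2675 and 1166 of 1211 genes.

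The totals of tables of selected genes are not the depth of a library, so depth was recovered from the deposited values. For the mitochondrially encoded genes, with single known lengths, count divided by FPKM was fitted against annotated length, and the slope gives the depth, with no residual above 0.341% of the value. The other libraries were set relative to hESC replicate 1 by the median ratio of count to FPKM over genes with at least 200 counts in both. The depths were 6.85e+06 and 4.07e+06 reads for hESC, 3.64e+06 and 3.38e+06 for NEP, and 3.55e+06 and 5.60e+06 for ME. The tables hold from 14.5% to 30.2% of those reads. Footprint levels are given as CPM, counts per 1000000 reads of that depth, as mean ± SD over 2 libraries. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

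The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust, two-sided) on the rounded counts with the recovered depths, normalization factors of 1 and no filter on low counts, with Benjamini-Hochberg adjustment over the genes of the table and a threshold of 0.05. Each comparison with hESC used its 4 libraries. NEP was set against ME in a fit of all 6 libraries over the 576 genes in both tables, whose hESC counts are identical in the 2 tables. Because every gene had already passed the authors' test on the same libraries, the number past this threshold shows how many calls held in another test, and neither that number nor an adjusted p is independent evidence. Tested on simulated data, with 200 of the genes changed by known folds, the step called 14% of genes changed 2-fold, 74% at 4-fold and 90% at 8-fold in 2675 simulated genes of the NEP comparison, and 0.242% of the unchanged genes. In 1211 simulated genes of the ME comparison it called 16%, 74% and 98%, and 0.989% of the unchanged genes. In 576 simulated genes of the comparison of NEP with ME it called 38%, 88% and 96%, and 1.33% of the unchanged genes.

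Where a group had no read for a gene, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3, the ratio of pooled counts per depth is given with its 95% interval (exact binomial). Footprint reads carry no molecular identifiers here, so floors and intervals cover counting error only.

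Before the data were examined, 27 gene lists were fixed: 22 lists of named markers and pathway genes and 5 lists by symbol (cytosolic and mitochondrial ribosomal proteins, mitochondrially encoded genes, histones, and zinc finger genes with symbols of ZNF and a number). A list was tested with a two-sided Fisher exact test (scipy 1.17.1) of its called members, higher against lower, against the other called genes of the same table, with adjustment over the lists with at least 3 listed members, 27 in NEP and 24 in ME. These tests compare a list only with other selected genes. Genes in the text follow a rule fixed at the same time: NAT10 and NR2F1, the 6 largest rises and 6 largest falls among called protein-coding genes with a mean count of at least 100 and no overlap between groups, the 3 largest changes of each list with at least 3 called members (mean count at least 50), the 3 most abundant called members of each lineage and feeder list, and for NEP against ME the 5 largest differences each way with the same limits. The rule ranks by fitted log2 fold change, in which a gene with no read in a group has no measured size. Any gene named outside this rule was chosen after its values were seen. Some results that this rule selects are not reported here.

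The alternatives were TMM factors on the table totals, the table totals alone, DESeq2 1.42.0 with its own size factors, only genes with a mean count of at least 50, a 2-fold minimum, the replicate number as a block, limma 3.58.1 on log2(FPKM + 1) and on log2(FPKM + 0.1), each library left out in turn, all 6 libraries in 1 fit, and the authors' deposited calls. Chosen after seeing the data were adjustment over the number of genes the authors tested, depth without mitochondrially encoded reads, crossed replicate blocks, a split of the hESC libraries between the lineages, and a fit of the NEP and ME libraries alone. Scaling matters in such tables: against the recovered depth, the median log2 fold change moved by -0.53 in NEP and -0.30 in ME with TMM, by 0.36 and 0.33 with the table totals, and by -1.16 and 0.59 with DESeq2. Genes that share sequence with close copies, such as LEFTY1 and LEFTY2, the histone genes, the muscle actin genes and TUBB2A, carry uncertain counts, since estimated counting divides shared reads between copies.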

Results

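Ribosome footprints, the short mRNA fragments that translating ribosomes shield from RNase, were counted per gene in 2 libraries each of hESC, NEP and ME. All came from H9, an established human embryonic stem cell line grown on mitomycin-treated mouse fibroblast feeders. NEP cells were kept for 6 days with 3 µM CHIR99021, a GSK3 inhibitor that activates Wnt signalling, 2 µM DMH1, an inhibitor of BMP receptors, and 2 µM SB431542, an inhibitor of the TGF-β and Nodal receptors. ME cells received 5 µM CHIR99021 for 36 h. The series concerns NAT10, the enzyme that acetylates cytidine in RNA, and the translation of NR2F1, a nuclear receptor of the neuroectoderm. The comparisons below ask which mRNAs gained or lost footprints in each lineage. Depth ranged from 3.38e+06 to 6.85e+06 reads per library, and the tables cover 2675 genes for NEP and 1211 for ME that the authors had selected as changed.

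In NEP, footprints of neural transcription factors and HOX genes rose, while those of pluripotency, epithelial and Nodal pathway genes fell. POU3F2, a neural POU-domain factor, had no read in either hESC library and 174 ± 34.2 CPM in NEP (SD, n = 2), at least 633-fold higher. LEF1, a transcription factor of the Wnt pathway, went from no read to 70.5 ± 0.530 CPM, at least 257-fold higher. ZEB2, a repressor of epithelial genes, rose 324-fold, from 1.52 ± 0.287 to 490.0 ± 21.6 CPM. At the other end, CDH1, which encodes E-cadherin, fell from 535 ± 301 CPM to no read in either NEP library, at least 1252-fold lower, and LEFTY1, a secreted Nodal antagonist, fell from 519 ± 310 CPM to no read, at least 1215-fold lower. NR2F1, at chromosome 5 from 93583222 to 93594611 (GRCh38), had no read in hESC and 84 and 57 reads in NEP, or 19.97 ± 4.39 CPM, at least 72.7-fold higher (adjusted p = 7.92e-06, edgeR).

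The fixed rule for large changes in NEP named further genes. MEIS1, a HOX cofactor, was at 91.7 ± 18.0 CPM in NEP, and 1 read in hESC gives a ratio of 1006 (95% interval 180 to 39797). For ILDR2, an immunoglobulin-like membrane protein, at 81.7 ± 25.1 CPM, the ratio was 899 (161 to 3.56e+04). For ZNF503, a zinc finger repressor, at 68.7 ± 16.3 CPM, it was 248 (84.4 to 1208). The falls it named were ranked by fitted log2 fold change, which tends to put genes with no read first, and included SERPINB9, an inhibitor of granzyme B (238 ± 180.5 CPM in hESC, at least 556-fold lower), LEFTY2 (170 ± 119 CPM, at least 398-fold), the neuropeptide precursor GAL (127 ± 17.8 CPM, at least 298-fold) and IDO1, an enzyme of tryptophan breakdown (103 ± 34.6 CPM, at least 241-fold). None of those 4 had a read in NEP. TDGF1, at least 284-fold lower, was left out of that ranking only because it had no biotype in the gene table.

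**Figure D1:**
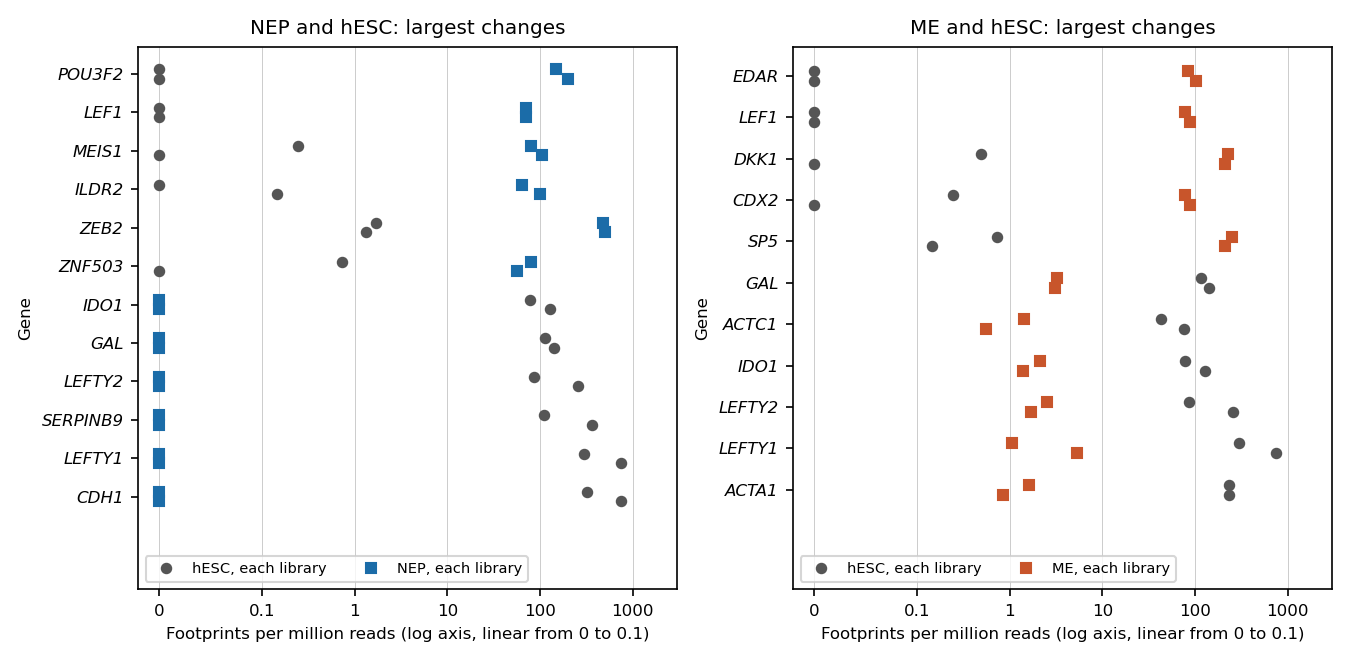
CPM in each library (x axis, logarithmic above 0.1 and linear below) for genes that the fixed rule named as large rises and falls in NEP (left) and in ME (right), with hESC as circles and the differentiated cells as squares. In NEP, after 6 days, the 6 genes that fell have no read in either library. In ME, after 36 h, all 6 genes that fell keep some reads, for example 3.21 ± 3.03 CPM for LEFTY1.

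Among 2675 genes, 1330 were higher and 1338 lower in NEP than in hESC, and 7 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg). The authors' deposited table lists 1331 and 1344. Since those lists had been selected on the same libraries, the agreement is not independent evidence. Of the genes, 79 had no read in hESC and 195 none in NEP. The number lower dropped to 873 without NEP replicate 1 and 835 without NEP replicate 2. With DESeq2, which changes both the test and the size factors, the higher and lower calls were 583 and 1345. That puts 30.2% of calls on the higher side against 49.9%.

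Pluripotency genes fell almost throughout in NEP. Of 20 listed members, 19 were lower and 1 higher (adjusted p = 0.000204, Fisher exact test against the other listed genes). POU5F1, the core pluripotency factor OCT4, chosen after its values were seen, was at 452 ± 3.09 CPM in hESC and 0.867 ± 0.448 CPM in NEP. L1TD1, an RNA-binding protein of stem cells, fell 156-fold, from 1024 ± 152 to 6.52 ± 1.27 CPM, PODXL, a surface sialomucin, fell 15.8-fold, and the DNA methyltransferase DNMT3B fell 4.88-fold, from 2005 ± 547 to 411 ± 64.7 CPM. TDGF1, a Nodal co-receptor, and the transcription factors ZSCAN10 and PRDM14 had no read in NEP, against 122 ± 65.1, 36.1 ± 19.1 and 33.8 ± 21.8 CPM in hESC. The member that rose was MYCN, from 111 to 345 CPM. The list of BMP and Nodal targets went the same way, with 12 of 13 lower and ID3 higher (adjusted p = 0.0113). NODAL itself was at 46.4 ± 30.1 CPM in hESC and 0.285 ± 0.0150 CPM in NEP, a ratio of 0.00550 (95% interval 0.000665 to 0.0200). With DESeq2 calls the adjusted p of this list was 0.260.

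Neuroectoderm genes rose, with 18 of 19 listed members higher (adjusted p = 0.000204, Fisher exact test) and OTX2, a forebrain factor, lower. SOX11 was among the most abundant, at 201 ± 17.2 CPM in hESC and 2958 ± 341 CPM in NEP, 14.7-fold higher. NES, which encodes the intermediate filament nestin, rose 3.07-fold, and CDH2, which encodes N-cadherin, rose 3.22-fold. PAX3, a dorsal neural tube factor, and ZBTB16 had no read in hESC and 33.0 ± 7.33 and 29.7 ± 1.96 CPM in NEP, at least 120-fold and 108-fold higher. All 13 listed members of the caudal neural and HOX list were higher (adjusted p = 0.000513). HOXB1, HOXA2 and HOXB3, hindbrain HOX genes, were at 56.1 ± 3.10, 48.4 ± 13.2 and 43.3 ± 5.59 CPM with no read in hESC. Of the neuronal list 3 of 5 were higher and 2 lower (adjusted p = 0.713): the cytoskeletal genes MAP2 and DCX rose 22.4-fold and 4.88-fold, and GAP43, a growth cone protein, fell 3.34-fold.

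Epithelial genes fell, with 20 of 21 listed members lower (adjusted p = 0.000177, Fisher exact test) and DSP, a desmosomal protein, higher. AP1M2, a sorting adaptor of epithelial cells, and the tight junction gene CLDN7 went from 66.9 ± 33.1 and 52.1 ± 34.0 CPM to no read. Of the mesenchymal list 6 of 7 were higher (adjusted p = 0.117), among them ZEB1, which rose 52.96-fold, and the matrix metalloproteinase MMP2, which rose 13.9-fold. Of the Wnt target list 10 of 12 were higher (adjusted p = 0.0536), including NKD1 (62.1-fold) and TNFRSF19 (45.4-fold), while MYC and FZD7 were lower. The adjusted p of that list was 0.0485 with TMM, 0.0171 with DESeq2 and 0.138 with table totals. Feeder fibroblast markers went mostly down, with 10 of 13 lower and 3 higher (adjusted p = 0.145, and 0.0363 among genes with a mean count of at least 50). COL1A1, a fibrillar collagen, fell 20.3-fold, from 693 ± 485 to 34.2 ± 0.183 CPM, and TAGLN fell 18.1-fold.

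All 21 listed histone genes were lower in NEP (adjusted p = 2.38e-05, Fisher exact test). H1-3, a linker histone, fell 5.50-fold, from 722 ± 122 to 131 ± 30.1 CPM, and H2BC21 and H2AC15 fell 4.395-fold and 4.26-fold. Fewer of them were called without either NEP library, though all 21 stayed below 0. Their median log2 fold change was -1.37 without NEP replicate 1 and -1.78 without NEP replicate 2, against -1.49 with all libraries. Zinc finger genes with ZNF symbols, a set that includes genes without a KRAB domain, were higher in 50 and lower in 14 of 64 (adjusted p = 4.42e-05). With DESeq2 calls 22 were higher and 14 lower (adjusted p = 0.00126), and with table totals 50 were higher and 7 lower. ZNF521 rose 15.0-fold and ZNF257 19.1-fold. ZNF257 was at 14.6 and 93.8 CPM in NEP replicates 1 and 2, and its log2 fold change was 5.05 without NEP replicate 1 and 2.36 without NEP replicate 2. The 9 listed mitochondrially encoded genes, which are translated on mitochondrial ribosomes, were all lower (adjusted p = 0.0116), with MT-ATP6 down 22.9-fold, from 6956 ± 3086 to 303 ± 154 CPM. Of 11 cytosolic ribosomal protein genes 10 were lower and 1 did not pass (adjusted p = 0.00741). Adjusted over the list alone, 9 were lower. RPL12 fell 3.92-fold. That list's adjusted p was 0.575 without NEP replicate 1 and 0.133 without NEP replicate 2. All 7 listed genes of hypoxia and glycolysis were lower (adjusted p = 0.0419, and 0.0720 without hESC replicate 1), led by the glucose transporter SLC2A3 (10.8-fold), ADM (7.42-fold) and SLC16A3 (5.57-fold). With DESeq2 calls the adjusted p was 0.175 for the mitochondrially encoded list, 0.123 for the ribosomal proteins and 0.259 for hypoxia and glycolysis.

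The remaining lists did not pass in NEP, some of them narrowly. All listed members were lower for cholesterol synthesis (5 of 5), ribosome biogenesis and RNA acetylation (6 of 6), heat shock and chaperones (6 of 6), the amino acid stress genes of ATF4 (4 of 4) and definitive endoderm (3 of 3), with adjusted p from 0.0645 to 0.355 (Fisher exact test). Lists of 3, 4 or 5 members could not pass in this test even with all members lower. The unadjusted p was then 0.250, 0.125 and 0.0623 (Fisher exact test), so their failure to pass says nothing about their direction. The nucleolar gene DKC1 fell 2.52-fold and the chaperone HSPA8 fell 4.02-fold. Mitochondrial ribosomal proteins were lower in 8 of 9 (adjusted p = 0.0747). Among genes with a mean count of at least 50, the adjusted p was 0.0318 for ribosome biogenesis and for chaperones, 0.0363 for mitochondrial ribosomal proteins and 0.0431 for cholesterol synthesis. Ribosome biogenesis and chaperones were at 0.0332 and 0.0154 without hESC replicate 1 and both at 0.0288 without hESC replicate 2, where mitochondrial ribosomal proteins were at 0.0371. Without NEP replicate 1 or NEP replicate 2, lower calls fell to 0 and 1 for ribosome biogenesis, 2 and 2 for chaperones and 3 and 1 for mitochondrial ribosomal proteins. Higher and lower members numbered 5 and 3 for mesendoderm, 2 and 5 for neural crest, 1 and 3 for trophectoderm and amnion, 3 and 3 for Notch, 1 and 4 for p53 targets, 1 and 3 for proliferation and 2 and 1 for translation factors. The adjusted p of these 7 lists ranged from 0.506 to 1. Among these DLL1, a Notch ligand, rose 19.0-fold and EIF3A, a subunit of the initiation factor eIF3, rose 2.38-fold. Apart from the ribosomal proteins, each list in NEP gave the same counts adjusted over the list alone.

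In ME, genes of the primitive streak, Wnt targets and genes of the caudal neural and HOX list rose, and pluripotency genes fell. MIXL1, a homeobox factor of the primitive streak, was at 127 ± 38.2 CPM in ME, with a ratio of 485 (95% interval 166 to 2355) over 3 reads in hESC, and TBXT, the mesoderm factor brachyury, chosen after its values were seen, was at 0.292 ± 0.413 CPM in hESC and 73.1 ± 13.3 CPM in ME. DKK1, a secreted Wnt antagonist, reached 218 ± 11.3 CPM, a ratio of 1198 (331 to 9901). LEF1 and EDAR, a receptor of the TNF family, had no read in hESC and 83.7 ± 7.48 and 92.7 ± 13.1 CPM in ME, at least 304.5-fold and 337-fold higher. NANOG, a core pluripotency factor, fell 7.03-fold, from 90.6 ± 1.20 to 12.8 ± 1.81 CPM (adjusted p = 1.13e-05, edgeR). NR2F1 was not analysed here for ME.

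CDX2, a caudal homeobox factor, rose to 82.8 ± 7.96 CPM, a ratio of 890 (159 to 35194) over 1 read in hESC, and SP5, a Wnt-induced zinc finger factor, rose 562-fold, to 229 ± 29.7 CPM. Among protein-coding genes with a mean count of at least 100 and no overlap between groups, the largest falls were those of ACTA1, the skeletal muscle actin (178-fold, from 232 ± 2.21 to 1.23 ± 0.539 CPM), LEFTY1 (169-fold) and LEFTY2 (78.9-fold), IDO1 (56.0-fold), the cardiac actin ACTC1 (55.1-fold) and GAL (39.9-fold).

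Among 1211 genes, 558 were higher and 588 lower in ME than in hESC, and 65 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg). The authors' deposited table lists 561 and 650, selected on the same libraries. In hESC 46 genes had no read, and in ME 44. The calls rested on both ME libraries: without ME replicate 1 there were 332 higher and 321 lower, and without ME replicate 2 there were 246 and 219. With DESeq2, in which the test and the size factors both differ, the higher and lower calls were 561 and 381. That puts 59.6% on the higher side against 48.7%.

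Of the mesendoderm and primitive streak list 13 of 15 were higher and 2 lower (adjusted p = 0.0129, Fisher exact test). WNT5B, a noncanonical Wnt ligand, reached 162 ± 10.4 CPM, a ratio of 595 (203 to 2890), and FGF17 rose 347-fold, to 134 ± 0.836 CPM. KDR, the VEGF receptor, fell 6.996-fold, and CER1, an antagonist of Nodal and BMP, fell 14.3-fold. Of the Wnt target list 14 of 16 were higher (adjusted p = 0.00929), including DKK4, with no read in hESC and at least 76.7-fold higher, while MYC and FZD7 were lower. All 9 caudal neural and HOX genes were higher (adjusted p = 0.00929), among them HOXB1, at least 130-fold, and NKX6-1, 71.1-fold. None of the mesendoderm, Wnt and HOX lists passed with table totals or among genes with a mean count of at least 50. The mesendoderm list was at 0.0550 without ME replicate 1, and with DESeq2 calls it was at 0.102 and the HOX list at 0.0526. Pluripotency genes were lower in 13 of 13 (adjusted p = 0.00289), with PRDM14 down 21.4-fold, TDGF1 7.03-fold, L1TD1 5.65-fold, DNMT3B 4.21-fold and PODXL 2.71-fold. The adjusted p of that list was 0.136 without ME replicate 1 and 0.0631 without ME replicate 2.

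Neuroectoderm genes were higher in 10 of 12 listed members in ME (adjusted p = 0.0641, and 0.0296 with TMM, Fisher exact test). PAX3 had no read in hESC and 30.8 ± 5.87 CPM in ME, at least 112-fold higher, SOX3 rose 12.4-fold, CDH2 5.49-fold and HES1 3.21-fold, and for DACH1 the ratio was 664 (119 to 26289). The 4 neuronal genes listed were higher (adjusted p = 0.149), among them MAP2 (10.3-fold), STMN2 (3.58-fold) and TUBB3 (2.72-fold). A list of 4 could not pass here even with all members higher, since the unadjusted p was then 0.0559 (Fisher exact test). Of the mesenchymal list 5 of 6 were higher (adjusted p = 0.184), with ZEB2 up 136-fold and MMP2 up 32.1-fold. Of the epithelial list 4 of 5 were lower (adjusted p = 0.473), with ST14 and GRHL2 down 3.81-fold and 3.65-fold, and DSP rose 7.88-fold. Feeder fibroblast markers were lower in 9 of 10 (adjusted p = 0.0641), with COL1A1 down 6.40-fold, THBS2 5.08-fold, COL5A2 4.98-fold and CCN2 4.97-fold. The adjusted p of that list was 0.0330 with table totals, 0.0428 with DESeq2 and 0.00506 among genes with a mean count of at least 50. Lower calls in it numbered 2 without ME replicate 1 and 0 without ME replicate 2.

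Histone genes rose in ME, with 19 of 21 higher, 1 lower and 1 not past (adjusted p = 0.000290, Fisher exact test). The linker histone H1-1 rose 3.97-fold, from 15.5 ± 2.45 to 61.7 ± 23.5 CPM, and H4C3 and H4C14, which encode the same H4 protein, rose 3.74-fold and 3.62-fold. Higher calls numbered 10 without hESC replicate 2, and 1 without ME replicate 1 and 0 without ME replicate 2, the last 2 with adjusted p = 1 for the list but a median log2 fold change of 1.75 and 1.25, against 1.52 with all libraries. All 10 listed mitochondrially encoded genes were lower (adjusted p = 0.00929), with MT-ATP6 down 8.68-fold, MT-ND4 7.53-fold and MT-ND2 6.79-fold. Lower calls numbered 6 without ME replicate 1 (adjusted p = 0.0827), 0 without ME replicate 2 (adjusted p = 1) and 5 without hESC replicate 2 (adjusted p = 0.158). As a share of recovered depth, the 9 mitochondrially encoded genes in both tables took 4.88% and 8.74% of reads in the hESC libraries, 0.597% and 1.37% in NEP, and 2.07% and 0.842% in ME.

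**Figure D2:**
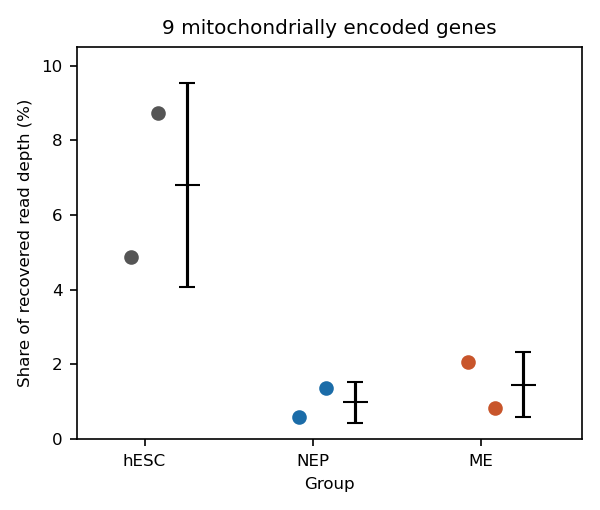
Share of recovered read depth taken by the 9 mitochondrially encoded genes in both tables, in percent, per library (circles, replicate 1 at left), with group mean ± SD (n = 2) beside them. The mean was 6.81 ± 2.73% in hESC, 0.983 ± 0.545% in NEP and 1.45 ± 0.866% in ME.

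No other list passed in ME. Cytosolic ribosomal proteins were higher in 7 and lower in 2 of 9 (adjusted p = 0.184, Fisher exact test), with RPS27L up 3.63-fold and RPL35A up 3.14-fold. Hypoxia and glycolysis genes were higher in 4 of 5 (adjusted p = 0.291), with PDK1 up 3.27-fold, ENO1 3.14-fold and LDHA, lactate dehydrogenase A, 2.89-fold. Higher calls fell to 3 and 1 in those 2 lists without hESC replicate 2, to 1 and 0 without ME replicate 1, and to 0 and 0 without ME replicate 2. The 3 listed proliferation genes were higher (adjusted p = 0.184): TYMS (5.38-fold), CDK1 (3.65-fold) and RRM2 (3.402-fold). Without ME replicate 1 or ME replicate 2, 1 of them was called higher in each case. The 3 listed p53 targets were higher as well (adjusted p = 0.184), with the cell cycle inhibitor CDKN1A up 6.63-fold, as were the 3 mitochondrial ribosomal proteins. A list of 3 could not pass here even with all members higher, since the unadjusted p was then 0.115 (Fisher exact test). Higher and lower members numbered 4 and 6 for BMP and Nodal targets, 2 and 3 for definitive endoderm, 4 and 3 for neural crest, 2 and 3 for trophectoderm and amnion, 1 and 3 for Notch, 3 and 1 for the amino acid stress genes, and 7 and 2 for the zinc fingers, with adjusted p from 0.184 to 1. MSX1, a BMP-responsive homeobox gene, had no read in hESC and 28.9 ± 6.52 CPM in ME, at least 105-fold higher. Of 6 translation factors 4 were higher, 1 lower and 1 did not pass, and adjusted over the list alone 5 were higher and 1 lower. The other lists gave the same counts adjusted over the list alone. Of cholesterol synthesis 2 genes were listed, both lower, of the chaperones 1, which did not pass, and of ribosome biogenesis and RNA acetylation 0.

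Both lineages were compared with the same hESC libraries. Of the 576 genes in both tables, 553 were called in both comparisons: 164 higher in both, 358 lower in both, 8 higher in NEP and lower in ME, and 23 lower in NEP and higher in ME. LEF1, ZEB2, MAP2, MMP2, HOXB1 and PAX3 were among those higher in both, and COL1A1, L1TD1, DNMT3B and LEFTY1 among those lower in both. Independent lists among 13594 genes would share 54.6 higher and 57.9 lower. Calls in the same direction, 522 in all, numbered 299 without ME replicate 2. Across the 576 genes the log2 fold changes had a Pearson correlation of 0.863 and a Spearman correlation of 0.788, and 94.6% had the same sign. Unchanged groups simulated against the same hESC libraries gave medians of 0.493, 0.474 and 66.1% over 100 draws. The simulated genes were not selected, while the 576 had each been listed as changed in both comparisons, which by itself can raise these measures. The authors listed 545 of the 576 in the same direction, so the same-sign share was set by the listing. The covariance was 9.32 against 0.133 simulated, a difference of 9.19. In 10 simulated draws 0 genes were called in both in the same direction (edgeR), an outcome close to fixed because nothing was changed in them. With the hESC libraries split, 1 for each lineage, in a test added after the results were seen, the covariance was 9.03 and 9.28 and the Pearson correlation 0.815 and 0.855 in the 2 possible ways, with 497 and 474 calls in the same direction. Each part then held 1 library, part of the excess may still come from the shared controls and from the selection of the genes, and genes are not independent replicates.

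**Figure D3:**
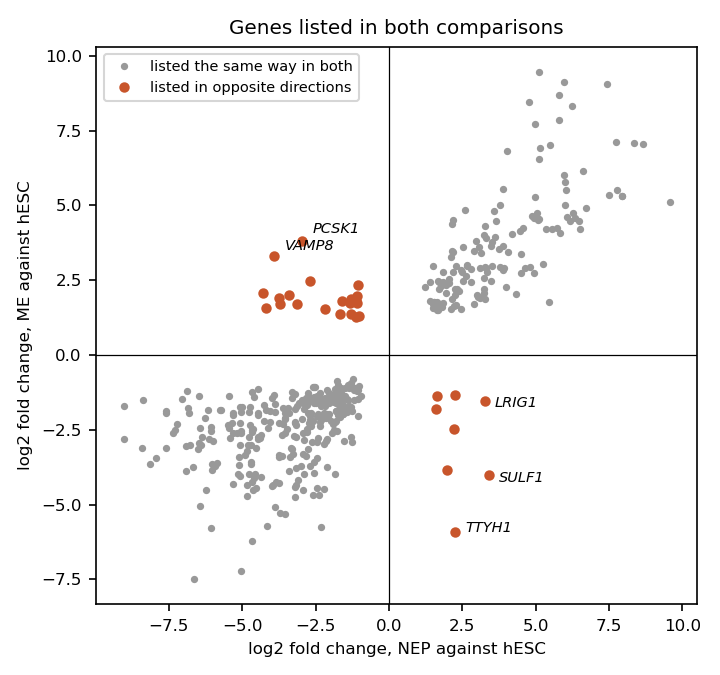
Log2 fold change against hESC in NEP (x axis) and ME (y axis) for the 477 genes in both tables with a read in every group; grey points are listed in the same direction in both and orange points in opposite directions. The 29 orange points are those of the 31 genes listed in opposite directions that have a read in every group, with TTYH1 at 2.27 and -5.93.

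Set directly against each other over those 576 genes, NEP had 43 genes higher and ME had 149 higher (edgeR quasi-likelihood test, 6 libraries). Among genes with a mean count of at least 100, the largest differences towards NEP were TTYH1, a membrane protein of neural cells (106 ± 24.5 CPM in NEP and 0.371 ± 0.272 in ME), the heparan sulphate sulphatase SULF1 (82.8 ± 9.56 and 0.512 ± 0.471), PKDCC, a secreted kinase (72.9 ± 24.4 and 1.34 ± 0.889), LRIG1, a negative regulator of receptor tyrosine kinases (862 ± 169 and 31.3 ± 4.34), and ANKRD13B (71.5 ± 11.01 and 2.86 ± 1.52). Towards ME the rule, which ranks by fitted log2 fold change, named MPP1 (53.3 ± 6.02 CPM in ME, at least 125-fold), AP1M2 (27.1 ± 0.859, at least 63.4-fold), the sodium channel subunit SCNN1A (14.3 ± 1.28, at least 33.5-fold), LAMC3 (13.2 ± 0.0127, at least 30.9-fold) and GALNT3 (10.4 ± 0.494, at least 24.2-fold), none with a read in NEP. Of those named towards ME, only MPP1 was higher in ME than in hESC, where it was at 13.8 ± 3.57 CPM. AP1M2, SCNN1A, LAMC3 and GALNT3 were lower in ME than in hESC, where they were at 66.9, 64.9, 50.7 and 54.9 CPM. For them the difference was a deeper fall in NEP, not a gain in ME. The adjusted p of these 10 genes ranged from 1.47e-06 to 6.40e-05. Genes with no read tend to come first in such a ranking, and VAMP8 and PCSK1, which kept reads in NEP, were 149-fold and 107-fold higher in ME. With other scalings NEP and ME had 56 and 114 genes higher (TMM) and 54 and 102 (table totals). DESeq2, which also changes the test, gave 68 and 109. Without NEP replicate 1 the calls were 24 and 95, without NEP replicate 2 there were 95 genes higher in ME, and without ME replicate 2 there were 24 higher in NEP. Only genes changed in both lineages could enter, which leaves out most lineage markers.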

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

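Of the tests below, the comparison of histone genes across scalings was chosen after the result was seen. Each result differed between NEP and ME, but only the genes listed in opposite directions were tested gene by gene between the lineages. Time and treatment also differed between NEP and ME and cannot be told apart from lineage. For the ribosomal protein and histone families, tallies of calls were compared between gene sets that the authors had selected separately.

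Of 576 genes in both tables, 31 were listed in opposite directions by the authors, 8 higher in NEP and lower in ME and 23 the reverse, and all 31 differed between NEP and ME (edgeR, adjusted p under 0.05). Because each listing needs at least a 2-fold change, this outcome was largely fixed by the selection. It was 30 without NEP replicate 1. VAMP8, PCSK1, ASS1, LDHA and PGM1 were lower in NEP and higher in ME, with NEP minus ME log2 differences of -7.22, -6.75, -5.41, -3.70 and -3.40, and MYCN and LFNG were higher in NEP and lower in ME, with 3.01 and 3.39.

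Cytosolic ribosomal protein genes were lower in 10 of 10 calls in NEP and higher in 7 of 9 in ME, though none was listed in opposite directions. The tallies differed with adjusted p = 0.00857 (Fisher exact test over 24 lists). That adjusted p was 0.0756 with TMM, 0.0667 with table totals, 0.000377 with DESeq2, 0.857, 0.381, 0.545 and 1 without NEP replicates 1 and 2 and ME replicates 1 and 2, and 0.00557 and 0.145 without hESC replicates 1 and 2. With TMM 4 were higher and 2 lower in ME, and with table totals 3 were lower in NEP. Lower calls in NEP numbered 1 without NEP replicate 1 and 3 without NEP replicate 2, and higher calls in ME 3 without hESC replicate 2, 1 without ME replicate 1 and 0 without ME replicate 2.

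Histone genes were lower in 21 of 21 calls in NEP and higher in 19 of 20 in ME, a difference with adjusted p = 1.96e-09 (Fisher exact test). The 2 sets overlap in part, only H1-1 and H3-3A were listed in opposite directions, and genes of a family are not independent replicates. Read recovery by length would move other short genes alike, yet of listed genes of the same length 55.6% were lower in NEP (p = 1.17e-05, Fisher exact test against histones) and 58.8% higher in ME (p = 0.00115). The test of scaling could not decide. The highest adjusted p over both comparisons and 4 scalings, DESeq2 among them, was 0.00588 (Fisher exact test). However, rescaling reversed no listed histone gene, and the authors' own scaling and thresholds had set which ones were listed. A difference between the cultures in the share of cells in S phase could give the same pattern and was not tested; in ME calls were lost, though the median log2 fold change was not, without ME replicate 1 (1 higher call, median 1.75, adjusted p of the difference 0.545), ME replicate 2 (0, 1.25, adjusted p = 1) and hESC replicate 2 (10, 1.06).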

How the results depend on the processing

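No gene named by the rule reversed, but each had been listed as changed on these same libraries, which made a reversal unlikely. For NEP and ME the alternatives also include the authors' own calls, which selected these genes. Of the values of those genes under the alternatives, 1287 of 1344 in NEP, 1169 of 1295 in ME and 160 of 160 between NEP and ME kept direction and side of the threshold, and the rest kept direction only. DESeq2, with its own test and size factors, gave 583 genes higher in NEP, 381 lower in ME and 68 higher and 109 lower in NEP than in ME. A mean count of at least 50 left 879 genes lower in NEP and 326 changed the same way in both, since fewer genes were tested. The fit of 6 libraries, over 576 genes, called 172 higher and 402 lower in NEP and 187 and 387 in ME. Adjusted over the number of genes the authors tested, chosen after seeing the data, 1324 were higher and 1002 lower in NEP, against 1330 and 1338. In ME 366 were higher and 401 lower, against 558 and 588. The main adjustment runs only over genes already selected as changed, so it is the more lenient. Leaving out each library in turn gave 1078 to 1329 higher and 835 to 1247 lower in NEP, 246 to 561 and 219 to 593 in ME, 24 to 60 and 95 to 182 for NEP against ME, 299 to 500 changed the same way in both, and 9 to 13 lists past the threshold in NEP and 2 to 6 in ME; the lone library of a group is then assumed to vary like the other groups. Without some library the fold moved by over 1.5 times for 28 of 61 genes named by the rule with a fitted fold in NEP and 31 of 66 in ME. In NEP 7 lists passed with DESeq2 and 14 among genes with a mean count of at least 50. For the other losses the cause was not tested. Same-numbered libraries did not deviate in the same direction (correlations 0.00889 for hESC and NEP, -0.470 for hESC and ME, -0.155 for NEP and ME), so the numbers were not taken as pairs. In hESC and ME they tended to deviate in opposite directions over 924 genes. For example, the histone gene H4C3 was at 472 and 139 CPM in hESC replicates 1 and 2, and at 945 and 1338 CPM in ME. The mitochondrially encoded share was 4.88% and 8.74% in hESC, and 2.07% and 0.842% in ME. Whether such replicate differences account for part of the ME family changes was not tested. With the replicate block, calls were 1330 higher and 1342 lower in NEP, 366 and 413 in ME and 46 and 147 for NEP against ME, and the adjusted p of the ME lists was 0.905 for histones and 0.802 for mitochondrially encoded genes. Crossed pairing gave 561 and 647 calls in ME and 53 and 160 for NEP against ME. In ME, table totals put the Wnt, HOX and mesendoderm lists at adjusted p = 0.0765, 0.0599 and 0.0954, and genes with a mean count of at least 50 at 0.0627, 0.398 and 0.398 (Fisher exact test). In NEP, table totals put the ribosomal proteins at 0.138 and the count filter put the HOX list at 0.0536. The authors' calls were not run for NEP against ME. Simulated 2-fold changes were called in 14% of cases in NEP, 16% in ME and 38% between NEP and ME.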

Other observations

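The gene families in this part, and the test of preparation differences, were chosen after the results were seen. The length and single-library tests of the respiratory chain had their predictions written before they were run.

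Muscle contractile genes fell in both lineages, in 16 of 19 listed genes in NEP (adjusted p = 0.00716, Fisher exact test over 5 families in both comparisons) and in 14 of 15 in ME (adjusted p = 0.00240). ACTA1 fell from 232 ± 2.26 to 2.27 ± 0.284 CPM in NEP, 100.5-fold, and 178-fold in ME. ACTN3, a sarcomeric actinin, fell 13.4-fold in NEP and 19.2-fold in ME, and TPM1, a tropomyosin, 10.6-fold and 14.7-fold. ACTA2, the smooth muscle actin, rose instead, 24.7-fold in NEP and 7.53-fold in ME. Counts of the muscle actin genes are uncertain, since shared reads are divided between close copies. TAGLN and ACTA2 were also on the feeder list. The unadjusted p was 0.118 in NEP with DESeq2 calls and 0.0555 in ME without ME replicate 2, where 6 genes were lower. Collagens were lower in 9 of 9 in ME (adjusted p = 0.00716; 4 lower calls without ME replicate 2 and 5 without ME replicate 1; COL1A1, COL5A2 and COL6A3 were also on the feeder list, which was lower in 9 of 10 in ME), while in NEP 15 were lower and 7 higher (adjusted p = 0.165), with COL2A1 up 34.3-fold.

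Solute carriers were lower in 39 of 52 listed genes in NEP (adjusted p = 0.00120, Fisher exact test), with 23 lower calls without hESC replicate 1. The amino acid transporter SLC7A5 fell 14.5-fold, the lactate transporter SLC16A1 5.31-fold and the zinc transporter SLC39A10 5.87-fold. In ME 7 were higher and 9 lower (adjusted p = 0.893). Protocadherins and neural adhesion genes were higher in 22 of 35 in NEP (adjusted p = 0.165) and 11 of 25 in ME (adjusted p = 1).

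Nuclear genes of the respiratory chain were lower in 20 of 20 in NEP (adjusted p = 1.78e-05, Fisher exact test) and higher in 19 of 22 in ME (adjusted p = 6.04e-05). Of listed genes of the same length 54.7% were lower in NEP (p = 8.74e-06, Fisher exact test against the family) and 61.1% higher in ME (p = 0.00222), which argues against length alone. Whether 1 library sets the pattern was not settled. The smallest median log2 change in the pattern's direction without each library in turn was 1.08, which met the limit written beforehand. That limit did not include the spread among members, which was weighed in addition. The SD was 2.05, or 0.730 without NDUFC2-KCTD14, a readthrough gene with no read in ME. Calls fell to 4 and 5 lower without NEP replicates 1 and 2, to 9 lower in NEP with table totals, and to 3 and 1 higher without ME replicates 1 and 2, where the family test gave p = 0.624 and 1 (Fisher exact test). Few genes were in both sets. COX6A1, 2.17-fold lower in NEP and 2.44-fold higher in ME, and ATP5MK (log2 fold changes -1.09 and 1.73) went opposite ways. ATP5ME (-1.79 and -1.17), NDUFB10 (-1.34 and -1.09) and NDUFC2-KCTD14 (-7.43 and -7.59) were negative in both.

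Mitochondrially encoded genes fell in both lineages. Scaling is unlikely to account for it, since the weakest median log2 fold change over both comparisons and 3 scalings was -1.69 (SD 0.627), nor does an excess in 1 hESC library, since without either of them it was at most -1.72 (SD 0.587). Of the listed nuclear genes of the respiratory chain 4.55% were called lower in ME, which argues against a fall of those listed genes as a set there. Respiratory chain genes that the authors had not selected were not covered. The ME set shares few genes with the NEP set, and ATP5ME, NDUFB10 and NDUFC2-KCTD14 had negative log2 fold changes in both. In NEP 100% were lower, so a fall of the whole chain stays open there. A footprint preparation that differed between groups remains possible: the hESC libraries themselves differed 1.79-fold in mitochondrial share, and no label gives a preparation batch.

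JUP, which encodes plakoglobin, was the 1 gene whose sign differed between the authors' FPKM ratio and the counts: counts were 548 and 127 in hESC and 102 and 82 in NEP, while FPKM was 52.7, 20.9, 12.3 and 151. Its implied length was 160.4 nt in NEP replicate 2 against 1519 nt in hESC replicate 1. Gene length and log2 fold change had Spearman correlations of 0.0945 in NEP and -0.187 in ME, and length and the ratio of the 2 ME libraries 0.331.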
